A study of Mus musculus with 24 samples.

How the data were processed

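Total RNA of whole mouse retina was measured on 24 Affymetrix oligonucleotide arrays. The samples came from mice lacking Nrl, a transcription factor of the rod lineage, and from wild-type controls. The labels describe both as of a matched mixed background of R1 and C57BL/6 strains. Each genotype was sampled at postnatal day 2 (P2), at P10 and at 2 months, with 4 replicates in each of the 6 groups. The labels do not say whether a replicate was 1 animal or a pool, so p-values measure only the spread between these samples. Sex-linked genes, given at the end, argue for pools of both sexes in the wild-type P10 samples and most knockout P2 samples.

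The deposited values are intensity values on a linear scale, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes. The version and which arrays were normalised together are not stated. Of 12488 probe sets, 66 array controls were left out and 12422 were tested. Exactly 1 gene symbol was attached to 10833 of them, several to 396 and none to 1193, which gave 8251 genes. A gene was represented by its probe set with the highest mean over the 24 arrays. Array medians lay between 61.9 and 71.8, and Pearson correlations across probe sets within groups lay between 0.983 and 0.997. The number of arrays limits the precision.

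Tests were run on log2 intensity in R 4.3.3 with limma 3.58.1. One model with 6 group means was fitted to the 24 arrays, with lmFit and eBayes, and contrasts were taken within it. They compared knockout with wild type at each age, the knockout effect between ages (interaction) and successive ages within each genotype. P-values were adjusted by the Benjamini-Hochberg method over the 12422 probe sets within each contrast. A gene was called at an adjusted p under 0.05, and calls with an absolute log2 change of at least 1 were also counted. Adjusted p-values for genes are from limma and two-sided. Intensities are given as mean ± SD (n = 4) and log2 changes as estimate ± standard error. Age and any processing batch that followed age cannot be told apart in the comparisons between ages.

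The genes named were set by a rule. For each knockout comparison it took Nrl, and the 10 largest rises and 10 largest falls among called genes whose 4 knockout values all lay on one side of the 4 wild-type values. For the other comparisons it took the 5 largest in each direction, for interactions by adjusted p alone. It also took up to 4 members of each gene list with the largest absolute change. Genes outside the rule are said to be so.

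The 21 lists were rod, cone, shared photoreceptor, Müller glia, reactive glia and injury, bipolar cell, amacrine and horizontal cell, ganglion cell, retinal pigment epithelium, lens, blood, microglia and macrophage, vascular, cell cycle, BMP signalling, Wnt signalling, glycolysis, heat shock and unfolded protein, immediate early, circadian and sex-linked genes. Of 324 listed genes 256 were measured. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists within a comparison. Camera compares a list with the other genes, and fry asks whether its genes move, on balance, one way. The lists, the comparisons, the gene rule and all alternatives but 2 were fixed before the data were examined. The BMP and Wnt lists hold pathways that the published study discusses on these samples.

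Array measures of RNA quality, carried-over tissue, sex-linked genes and clock genes were compared between genotypes with exact two-sided permutation tests of 4 against 4 arrays, whose smallest p is 0.0286. Positions of genes relative to Nrl, within 20 Mb, were taken from mouse assembly GRCm38.p6, and the share of called genes there was compared by Fisher's exact test.

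The steps were tested on simulated data with 50 changed genes at each of 4 sizes. At a log2 change of 0.5 they recovered 76%, 84% and 86% of the changed genes for P2, P10 and 2 months, and at 1 they recovered 100%, with 10, 9 and 5 false calls. The simulated noise was independent between probe sets, without effects shared within an array or a replicate number. False calls in the real data can therefore be more. Alternatives were quantile normalisation or median centring on top of the deposited values, a filter on dim probe sets, trended and robust moderation, array weights, stricter thresholds, a pseudocount of 16, a fit to only the arrays compared, a block for the replicate number and leaving out each replicate in turn. Leaving out 2 P2 arrays together and the replicate number as a block over all ages were added after the data were seen. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.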

Results

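At P2, retinas without Nrl carried less RNA for several photoreceptor genes. Sag, rod arrestin, stood at 245 ± 59.8 in wild type and 45.5 ± 12.7 in knockout retina (SD, n = 4), and fell by 2.44 ± 0.17 on the log2 scale (adjusted p = 4.79e-10). Pdc, phosducin, which binds transducin, fell from 379 ± 32.2 to 83.8 ± 16.1, Pde6b, a rod phosphodiesterase subunit, from 46.0 ± 3.96 to 17.7 ± 2.58, and Rom1, a protein of outer segment disc rims, from 71.3 ± 3.44 to 29.7 ± 6.00. Among genes that rose were Ssr1, a subunit of the translocon-associated complex, by a log2 change of 1.18 ± 0.10, the basement membrane collagen Col4a1 by 0.96 ± 0.10, Rb1, the retinoblastoma gene, which lies within 20 Mb of Nrl, by 0.68 ± 0.09, and Dlx2, a homeobox gene, by 0.71 ± 0.09. Snhg6, a small nucleolar RNA host gene, averaged 124 in knockout retina, where its 4 values ran from 44.8 to 211, against 321 ± 12.7 in wild type (adjusted p = 0.0223). Its call was lost without knockout replicate 2 or 4 or wild-type replicate 1, 2 or 3 (adjusted p = 0.113, 0.142, 0.0581, 0.0550 and 0.0694). Other probe sets of Ssr1, Rb1, Pdc, Pde6b, Rom1 and Snhg6 did not pass, with log2 changes of 0.10, 0.40, -0.39, -0.46, -0.27 and -0.05. Nrl itself did not pass the test at P2, with 60.4 ± 0.744 in wild type and 51.3 ± 5.13 in knockout retina (adjusted p = 0.30). All 4 knockout values of Nrl nevertheless lay below all 4 wild-type values (exact permutation p = 0.0286). The labels do not say whether its probes lie in the deleted part.

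Of 14 measured shared photoreceptor genes, 5 fell and 0 rose at P2, and 6 fell adjusted over the list alone, with a median log2 change of -0.19 (camera adjusted p = 3.3e-09; adjusted p = 0.0137 with an estimated correlation). Among 8 measured rod genes Pde6b alone fell, and 2 fell adjusted over the list alone. The rod list did not pass by camera (adjusted p = 0.0566) and passed by fry (adjusted p = 0.0128). Gnat2, cone transducin alpha, was the 1 of 8 cone genes that rose, from 81.4 ± 21.4 to 118 ± 11.4, with 4 adjusted over the list alone (camera adjusted p = 0.0177, but adjusted p = 0.171 with an estimated correlation and 0.118 by camera without knockout replicate 3). The cell cycle list shifted upward with 2 of 22 members called, 6 adjusted over the list alone. These were Pcna, the replication clamp, at 0.42 ± 0.10, and the helicase gene Mcm3 at 0.31 ± 0.08 (camera adjusted p = 0.000158, but adjusted p = 0.171 with an estimated correlation). Gap43, a growth cone gene, was the 1 of 10 ganglion cell genes called, 4 adjusted over the list alone (camera adjusted p = 0.000862; adjusted p = 0.169 with an estimated correlation). Tpi1, Pgk1 and Pgam1 rose and Aldoc fell among 14 glycolytic genes, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000747; adjusted p = 0.311 with an estimated correlation and 0.0661 by fry). The heat shock list shifted upward and the microglia list downward by camera (adjusted p = 0.0177 and 0.0185), and the adjusted p was 0.488 and 0.311 with an estimated correlation and 0.245 and 0.0661 by fry. In the BMP list Id2, an inhibitor of differentiation, rose, 1 of 16, with 2 members changed adjusted over the list alone, and the Wnt list did not pass (camera adjusted p = 0.408). The published study discusses both pathways on these samples, so these counts are not independent evidence. The lens list median stood 0.27 higher in knockout P2 arrays (exact permutation p = 0.714). Camera's adjusted p for lens genes was 0.523, but 0.0120 without knockout replicate 1 and 0.0430 without wild-type replicate 1, with higher values in the knockout. Without the same arrays that of the heat shock list was 0.0902 and 0.0640, and that of the microglia list was 0.0529 and 0.0694 without knockout replicates 1 and 2. Camera adjusted p-values were 0.975 for Müller glia, 0.531 for reactive glia and 0.805 for immediate early genes. Of 12 circadian genes Tef fell, 3 adjusted over the list alone, and the list passed by fry (adjusted p = 0.0205) but not by camera (adjusted p = 0.115, and 0.185 with an estimated correlation). The circadian list median was lower in all 4 knockout arrays than in all 4 wild-type arrays, with a difference of -0.17 (exact permutation p = 0.0286, adjusted p = 0.22). Xist, expressed in female cells, averaged 213 ± 68.3 in knockout and 59.8 ± 60.5 in wild-type retina (adjusted p = 0.13), with all 4 knockout arrays above all 4 wild-type arrays.

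At P2 limma called 175 of 12422 probe sets, 112 higher and 63 lower in knockout retina, 10 of them by at least 2-fold. Another of the 35 splits of the P2 arrays gave more calls, 267, and the count depended on single arrays. It was 84, 111 and 552 without knockout replicates 4, 2 and 3, and 100 and 93 without wild-type replicates 1 and 3. With only the arrays compared 23 probe sets were higher and 18 lower, and with array weights 311 and 103. The count was 464 with the replicate number as a block over all ages, a setting chosen after the data were seen, under which the highest other split gave 67. Without knockout and wild-type replicate 1 together, a setting chosen after the data were seen, it was 88, and camera adjusted p-values were 0.147 for cell cycle, 0.0596 for glycolysis, 0.337 for heat shock and 0.115 for microglia genes.

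**Figure D1:**
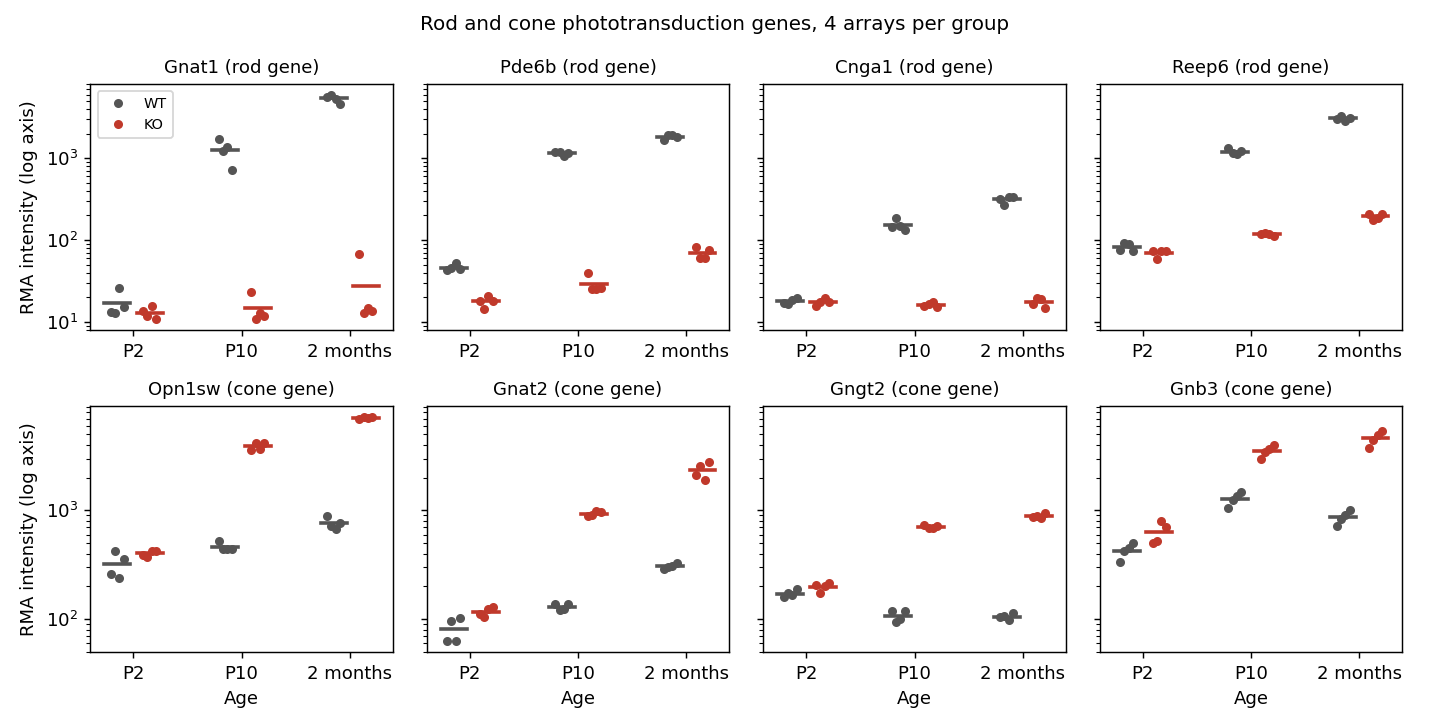
Intensity on a log axis of 4 rod genes (top) and 4 cone genes (bottom) at P2, P10 and 2 months, with 1 point per array, 4 arrays per group, and a bar at each group mean. Gnat1 averaged 5386 in wild-type and 27.3 in knockout retina at 2 months, and Opn1sw 762 and 7122.

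At P10 rod genes were low and cone genes high in knockout retina. Gnat1, rod transducin alpha, stood at 1249 ± 404 in wild type and 14.6 ± 5.70 in knockout (log2 change -6.42 ± 0.35, adjusted p = 8.38e-14), and Pde6b fell from 1148 ± 64.2 to 28.8 ± 7.13. Reep6, an endoplasmic reticulum protein of rods, and Cnga1, the rod cyclic nucleotide-gated channel, fell by 3.36 ± 0.09 and 3.24 ± 0.10 on the log2 scale. Knockout values of Gnat1 and Cnga1 lay near those of P2 retina, where Gnat1 averaged 16.8 in wild type and 13.0 in knockout and Cnga1 17.9 and 17.5. The files do not tell such levels from background, so the size of the log2 changes of both genes, at 2 months and between ages too, is uncertain. Pde6b read 14.2 to 20.4 in knockout P2 retina, near these levels. The size of its change at P2 and between ages is therefore uncertain too. Opn1sw, the short-wavelength cone opsin, rose from 464 ± 43.6 to 3902 ± 299, Gnat2 from 130 ± 8.91 to 935 ± 52.4, and Gngt2, a cone transducin gamma subunit, from 108 ± 12.1 to 709 ± 24.1. The largest rise was that of Gas2, an actin-associated protein, at 3.67 ± 0.19. Guca1a, an activator of guanylate cyclase, and Sall3, a zinc finger gene, rose by 2.50 ± 0.19 and 1.82 ± 0.09, and Drd4, a dopamine receptor, fell by 2.19 ± 0.19. Nrl fell from 135 ± 14.4 to 49.7 ± 5.18 (adjusted p = 7.88e-11).

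Of 8 measured rod genes 6 fell at P10, and 7 fell and 1 rose adjusted over the list alone (median -2.17; camera adjusted p = 2.56e-29; adjusted p = 3.75e-08 with an estimated correlation). Gnb1, a transducin beta subunit, did not pass by its brightest probe set, at 168 ± 34.0 and 221 ± 19.5. Its other probe sets, singled out after their values were seen, went apart, at 187 ± 7.79 and 43.1 ± 6.25 for one (log2 change -2.12, adjusted p = 1.70e-13) and at 95.1 ± 27.2 and 141 ± 14.9 for the other (log2 change 0.61, adjusted p = 0.0559). Of 8 cone genes 6 rose and 1 fell, the same numbers adjusted over the list alone (median 1.42; camera adjusted p = 5.97e-20; adjusted p = 7.13e-06 with an estimated correlation). The member that fell was Opn1mw, the medium-wavelength opsin, at -0.96 ± 0.17. Of 14 shared photoreceptor genes 9 fell and Guca1a rose, with 13 lower adjusted over the list alone (camera adjusted p = 4.14e-26; adjusted p = 1.19e-05 with an estimated correlation). Apoe, a lipid carrier, rose by its brightest probe set (another stood at a log2 change of 0.10, adjusted p = 0.90) and Aqp4, a glial water channel, fell among 10 Müller glia genes, with 1 higher and 3 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.731). Of 9 pigment epithelium genes Pmel, Ttr and Rgr, the last within 20 Mb of Nrl, fell, 3 also adjusted over the list alone (camera adjusted p = 0.0143; adjusted p = 0.256 with an estimated correlation, and 0.0863 by camera without wild-type replicate 3). Camera adjusted p-values were 0.408 for reactive glia, 0.698 for bipolar, 0.820 for amacrine and horizontal, 0.0865 for vascular (0.0277 without knockout replicate 1) and 0.818 for blood genes. Xist averaged 213 ± 52.8 in knockout and 94.3 ± 21.0 in wild-type retina (adjusted p = 0.74), and again all 4 knockout arrays lay above all 4 wild-type arrays. The adjusted p rests on a spread shared by the 6 groups, and not on that at P10 alone. Xist ran from 7.43 to 126 in wild-type P2 and from 8.90 to 209 in knockout 2 month retina. The BMP and Wnt lists both had a camera adjusted p of 0.818, and are not independent evidence.

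At P10 limma called 605 probe sets, 350 higher and 255 lower, and 73 changed by at least 2-fold. The 2 directions were near even with quantile normalisation, at 358 and 356, and with each array centred on its median, at 283 and 269, and were 949 and 452 with array weights. With the replicate number as a block over all ages, chosen after the data were seen, limma called 922.

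At 2 months rod genes were low and cone genes high again, and genes of glial reaction had risen. Gnat1 fell from 5386 ± 562 to 27.3 ± 27.0, where 3 of 4 knockout values lay between 12.9 and 14.8 (log2 change -8.03 ± 0.35, adjusted p = 2.88e-16), Reep6 from 3083 ± 178 to 194 ± 18.2 and Cnga1 from 314 ± 34.7 to 17.4 ± 2.13. Opn1sw rose from 762 ± 89.7 to 7122 ± 157 and Gnb3, a cone transducin beta subunit, from 866 ± 119 to 4632 ± 715. Clca1, a chloride channel regulator, rose by 4.01 ± 0.16, Fabp7, a brain fatty acid-binding protein, by 2.96 ± 0.14, and Pygm, muscle glycogen phosphorylase, by 2.18 ± 0.15. Aqp1, a water channel, fell by 3.02 ± 0.12, Gas5, a small nucleolar RNA host gene, by 2.65 ± 0.14 by its brightest probe set, Tnfaip3, an inhibitor of NF-kappaB, by 2.13 ± 0.15 and the transcription factor gene Mef2c by 2.04 ± 0.14. A further Gas5 probe set read 65.9 ± 4.63 in wild type and 58.5 ± 6.81 in knockout (adjusted p = 0.33), and another lay below 10 in all groups. Dimmer probe sets of Clca1, Aqp1 and Fos did not pass either, with log2 changes of 0.15, -0.13 and 0.07. Nrl stood at 145 ± 29.3 and 54.5 ± 6.01 (adjusted p = 7.11e-11).

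Of 8 rod genes 7 fell, 7 also adjusted over the list alone (median -2.78; camera adjusted p = 1.22e-26; adjusted p = 8.09e-08 with an estimated correlation). Gnb1 stood at 188 ± 54.9 in wild type and 211 ± 14.6 in knockout by its brightest probe set. Its other probe sets, singled out after their values were seen, again went apart. They stood at 371 ± 78.7 and 37.3 ± 4.52 for one and at 81.5 ± 25.3 and 137 ± 8.90 for the other. Of 8 cone genes 6 rose, 7 adjusted over the list alone (median 2.02; camera adjusted p = 3.81e-24; adjusted p = 1.66e-06 with an estimated correlation), and of 14 shared photoreceptor genes 7 fell, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.19e-09; adjusted p = 0.00462 with an estimated correlation). Of 14 genes of glial reaction and injury 9 rose and 1 fell, the same numbers adjusted over the list alone (median 0.59; camera adjusted p = 8.34e-11; adjusted p = 0.00462 with an estimated correlation). Serpina3n, a protease inhibitor of reactive astrocytes, rose from 103 ± 7.77 to 294 ± 57.2, Socs3, a brake on cytokine signalling, from 93.1 ± 4.69 to 221 ± 30.4, and Gfap, an intermediate filament of reactive glia, by 0.61 ± 0.09, while Edn2 fell. Apoe and Clu, the latter within 20 Mb of Nrl, rose among 10 Müller glia genes, 3 adjusted over the list alone (camera adjusted p = 0.00365, but adjusted p = 0.104 with an estimated correlation). A dimmer Apoe probe set did not pass, with a log2 change of -0.10 (adjusted p = 0.87). In the microglia list Ctss, C1qa and C1qc rose, 4 genes adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.0839; 0.0146 without knockout replicate 4 and 0.0360 without wild-type replicate 2) and passed by fry (adjusted p = 0.0379).

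Of 14 glycolytic genes 7 fell at 2 months, 8 adjusted over the list alone, among them the phosphofructokinase genes Pfkp and Pfkl at -0.82 ± 0.11 and -0.66 ± 0.09 (median -0.31; camera adjusted p = 2.97e-05, but adjusted p = 0.246 with an estimated correlation). Members of the chaperone list went both ways, with 4 of 17 higher and 4 lower, and 5 and 4 adjusted over the list alone. Hspa1b and Hspa1a, the inducible Hsp70 genes, fell by 1.71 ± 0.09 and 1.38 ± 0.09 and Hsph1, an Hsp70 cofactor, rose by 1.24 ± 0.10 (camera adjusted p = 0.705). Fos, an immediate early transcription factor gene, fell by 1.01 ± 0.19, and of 15 genes on its list 4 fell and 2 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.218, and 0.0292 without knockout replicate 4; fry adjusted p = 0.0484). The clock-controlled genes Dbp and Tef rose and Arntl, a core clock gene, fell, among 12 circadian genes, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.579). Dbp ran from 134 to 153 in wild-type and from 204 to 250 in knockout arrays, and Arntl from 199 to 241 and from 137 to 169. Members of this list moved in opposite directions. Its camera test and its median can therefore miss a difference in the hour of collection, which was not tested. Of 11 lens genes, Crygb, Crygc and Crygs, crystallins of the lens, fell, 6 adjusted over the list alone (median -1.18; camera adjusted p = 0.000786, but adjusted p = 0.374 with an estimated correlation). A dimmer Crygb probe set did not pass, with a log2 change of -0.51 (adjusted p = 0.0956). The lens list median per array differed by -1.07 between knockout and wild type (exact permutation p = 0.0286, adjusted p = 0.22). In the Wnt list Frzb, a secreted inhibitor, and Wnt5a rose, 2 of 27, and in the BMP list Acvr1 rose, 1 of 16, the same numbers adjusted over the list alone and not independent evidence. Camera adjusted p-values were 0.271 for bipolar (0.00502 by fry, downward), 0.541 for amacrine and horizontal, 0.397 for ganglion cell, 0.381 for pigment epithelium, 0.309 for vascular, 0.476 for cell cycle, 0.595 for blood and 0.595 for sex-linked genes. The sex-linked list joins Xist with Y-linked genes, which a difference in sex moves in opposite directions. Its test and its median therefore cannot show such a difference.

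At 2 months limma called 942 probe sets, 530 higher and 412 lower, and 139 changed by at least 2-fold. The balance turned to 411 higher and 427 lower without knockout replicate 4. Of the probe sets called at P10, 193 were also higher and 136 also lower at 2 months, against 14.9 and 8.46 expected if calls at both ages were independent, and 25 probe sets were called in one direction at all 3 ages, 49 with the replicate number as a block over all ages.

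**Figure D2:**
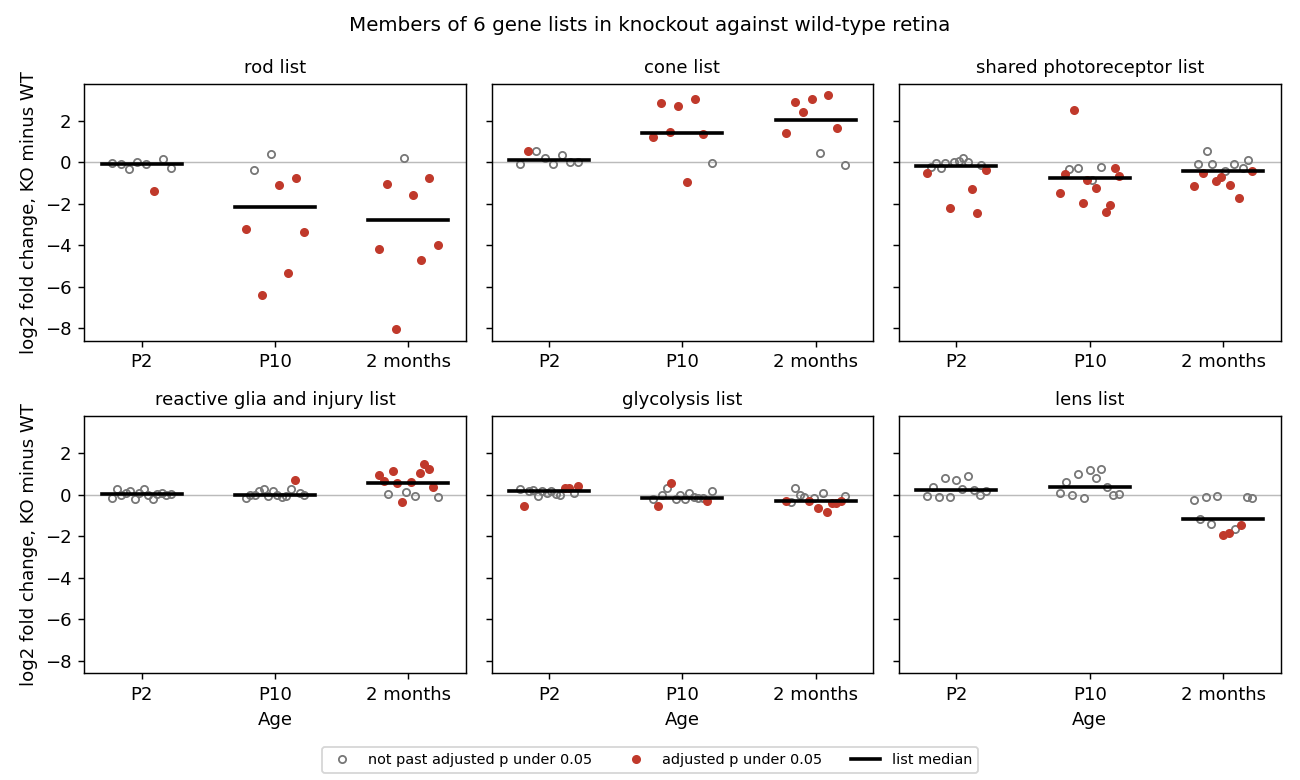
Log2 fold change of knockout over wild type for each measured member of 6 gene lists at P2, P10 and 2 months. Each point is 1 gene, filled at an adjusted p under 0.05, and bars mark list medians. The rod median went from -0.09 at P2 to -2.78 at 2 months and the cone median from 0.10 to 2.02.

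The effect of the knockout differed between ages. From P2 to P10 the effect on Gnat1 dropped by 6.10 ± 0.50 log2 units and that on Pde6b by 3.96 ± 0.18, both of uncertain size. The deposited values do not tell Gnat1 in both P2 groups and knockout P10 retina, or Pde6b in knockout P2 retina, from background. The effects on Gas2 and Opn1sw rose by 3.37 ± 0.28 and 2.70 ± 0.17. For this difference limma called 276 probe sets, 147 higher and 129 lower. The balance turned to 108 higher and 141 lower with each array centred on its median and to 174 and 184 with quantile normalisation. With the replicate number as a block over all ages, chosen after the data were seen, 432 were called. Of 8 rod genes 6 moved lower and of 8 cone genes 6 moved higher, the same numbers adjusted over the list alone (adjusted p = 4.11e-08 and 1.09e-05 with an estimated correlation). From P10 to 2 months 295 probe sets were called, 151 higher and 144 lower, and 223 and 252 with array weights. The effect on Clca1 rose by 2.22 and that on Sag by 1.77, and those on the crystallin genes Crygb and Crygc dropped by 3.14 and 2.66. The size for Crygb is uncertain, since it averaged 17.0 in wild-type P10 and 18.5 in knockout 2 month retina. Both crystallin calls were lost with trended and robust moderation (adjusted p = 0.165 and 0.132). They were also lost without single arrays, with adjusted p up to 0.118 and 0.0857, both without knockout P10 replicate 2, and that of Crygb with a pseudocount of 16 (adjusted p = 0.0668) and with the replicate number as a block over all ages (adjusted p = 0.0512). Serpina3n and A2m, protease inhibitors, moved higher, as did 7 of 14 genes of glial reaction and injury, 8 adjusted over the list alone (adjusted p = 0.00752 with an estimated correlation). From P2 to 2 months 584 probe sets were called, 288 higher and 296 lower, with Clca1 at 4.22 and Gnat1 at -7.71.

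In wild-type retina from P2 to P10 rod and shared photoreceptor genes rose and proliferation genes fell. Gnat1 rose from 16.8 to 1249, Pde6g, a rod phosphodiesterase subunit, from 192 to 3619 and Rcvrn, recoverin, from 60.4 to 1091, and Ccnd1, cyclin D1, fell from 2150 to 105 and Mki67, a marker of dividing cells, from 276 to 14.3. All 14 shared photoreceptor genes rose, as did 7 of 8 rod genes, and 20 of 22 cell cycle genes fell, the same numbers adjusted over the lists alone but for 1 further rod gene that fell (adjusted p = 0.000166 with an estimated correlation for each list). Of 8 cone genes 5 rose and 2 fell, the same numbers adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.296) and passed by fry (adjusted p = 0.00129). The call covered 4187 probe sets, 2032 higher and 2155 lower, but 3273 higher and 2415 lower with array weights. From P10 to 2 months 1866 probe sets were called, 917 higher and 949 lower, and 740 and 1072 with each array centred on its median. Sgk1, a serum- and glucocorticoid-regulated kinase, rose from 23.0 to 474, Hk2, a hexokinase, from 114 to 1422 and Guca1a from 286 to 3475, and Nnat, an imprinted neuronal gene, fell from 753 to 92.6. Of 14 glycolytic genes 12 rose (adjusted p = 0.0152 with an estimated correlation) and of 12 circadian genes 8 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.00104 with an estimated correlation).

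In knockout retina from P2 to P10 Sag rose from 45.5 to 984, Opn1sw from 403 to 3902 and Gnat2 from 118 to 935, while Mki67 fell from 338 to 14.3 and Myb, a proto-oncogene, from 1378 to 122. Of 8 cone genes 7 rose and of 22 cell cycle genes 20 fell, and 3 of 8 rod genes rose, the same numbers adjusted over the list alone. The rod list did not pass by camera (adjusted p = 0.0517) and passed by fry (adjusted p = 3.82e-11). The call covered 4015 probe sets, 2216 higher and 1799 lower, but 1712 higher and 2075 lower with each array centred on its median. From P10 to 2 months 2389 probe sets were called, 1007 higher and 1382 lower. Opn1mw rose from 79.8 to 630, Clu, clusterin, from 222 to 1465, Vtn, vitronectin, from 176 to 1148 and Cebpd, a transcription factor gene of the acute phase, from 49.3 to 188, and Mycn fell from 184 to 36.7. Across probe sets, which are not independent replicates, changes from P2 to P10 in the 2 genotypes had a Pearson r of 0.879 and those from P10 to 2 months 0.744. Of probe sets called in wild type, 72.0% and 70.2% were called in the same direction in the knockout.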

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

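The tests of genes outside the Nrl window, of P2 calls near Nrl, of RNA quality at P2 and P10 alone, of crystallin covariation, of other neuron genes, of splits with the mean knockout effect taken out and of P2 splits with a replicate block were chosen only after the result was seen.

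A group of 4 arrays was singled out where 1 value lay far from the other 3, which chance does in about 1 in 20 groups. This held for 5 of 72 array measures and 6 of 120 groups of named genes. At P2 the lens list median of wild-type replicate 1 was 0.17 against -0.77 to -0.75 in the others, and the blood list median of knockout replicate 1 was -0.68 against -0.21 to -0.12. Knockout P2 replicate 1 had a median intensity of 61.9 against 69.1 to 70.5. Nrl read 61.5 in wild-type P2 replicate 1 against 59.9 to 60.1, and 189 in wild-type 2 month replicate 4 against 129 to 134. Sag read 26.7 in knockout P2 replicate 2 against 49.1 to 53.4, and Pkig, a protein kinase inhibitor gene, 488 in wild-type P2 replicate 4 against 458 to 459. At P10 Opn1sw read 529 in wild-type replicate 1 against 438 to 445, Wwc1 71.3 in wild-type replicate 2 against 88.9 to 91.7 and Pde6b 39.5 in knockout replicate 1 against 24.9 to 26.0. Gnat1 read 67.8 in knockout 2 month replicate 1 against 12.9 to 14.8.

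The knockout effect differed between ages by the interaction test for 276 probe sets from P2 to P10, 295 from P10 to 2 months and 584 from P2 to 2 months. From P2 to P10 the differences in log2 effect were 3.37 for Gas2, 2.77 for Guca1a, 2.70 for Opn1sw, 2.52 for Gngt2 and 2.29 for Wwc1, and -6.10 for Gnat1, -3.96 for Pde6b, -3.20 for Cnga1, -3.11 for Reep6 and -1.96 for Drd4. From P10 to 2 months they were 2.22 for Clca1, 1.82 for Pygm, 1.77 for Sag, 1.65 for Fkbp9 and 1.50 for En2, and -3.14 for Crygb, -2.66 for Crygc, -2.64 for Gas2, -2.58 for Aqp1 and -2.03 for Mef2c. From P2 to 2 months they were 4.22 for Clca1, 2.86 for Gngt2, 2.86 for Opn1sw, 2.79 for Fabp7 and 2.60 for Fkbp9, and -7.71 for Gnat1, -4.14 for Cnga1, -3.74 for Reep6, -3.34 for Pde6b and -2.90 for Aqp1. The sizes for Gnat1 and Cnga1 are uncertain, since the files do not tell their values in P2 and knockout retina from background. The same holds for Pde6b, at 14.2 to 20.4 in knockout P2 retina. It also holds for Crygb, which averaged 17.0 in wild-type P10 and 18.5 in knockout 2 month retina. Over the same steps the rod list median differed by -2.06, -0.55 and -2.40 and the cone list median by 1.34, 0.23 and 1.75. The shared photoreceptor median differed by -0.30 from P2 to P10 and 0.27 from P10 to 2 months, and the reactive glia median by 0.41 from P10 to 2 months and 0.40 from P2 to 2 months.

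The arrays were split in other ways into groups of the same sizes. At P2, 2 of 35 splits, the real one included, gave at least 175 calls, so chance was not excluded for the count in fits that leave out the replicate number. The other gave 267, with knockout replicate 3 and wild-type replicate 4 exchanged. The numbers share an effect over the 24 arrays. With the number as a block over all ages, 1 of 35 splits reached the real count, 464 (highest other 67). This does not exclude chance either, since the block was chosen after the plain splits were seen. Many of the other splits also do not hold each number once per group, as the real one does. At P10 1 of 35 splits gave 605 and the highest other 0, and at 2 months 1 of 35 gave 942 and the highest other 12. Both argue against chance, but 1 of 35 is the smallest share that this test can give. The other splits at these ages share the limit of the replicate number. For the differences between ages, each probe set's mean knockout effect over both ages was taken out first, since exchanged genotypes otherwise turn an effect shared by both ages into a difference. With this step 1 of 100 splits reached 276 from P2 to P10 (highest other 131). From P10 to 2 months 1 of 100 reached 295 (highest other 3), and from P2 to 2 months 1 of 100 reached 584 (highest other 303). These counts argue against chance, but the step was chosen after the plain splits were seen and uses an effect estimated from the real groups. Without it 4, 5 and 1 of 100 splits gave as many calls (highest others 440, 812 and 505). By these plain splits, the test set first, chance was not excluded from P10 to 2 months, though they carry the shared effect. For wild type, 1 of 35 splits reached the real count from P2 to P10 (4187, highest other 367), and 1 of 35 from P10 to 2 months (1866, highest other 2). For the knockout it was 1 of 35 (4015, highest other 3) and 1 of 35 (2389, highest other 5). The splits between successive ages thus argue against chance, with the same limits as those at P10 and 2 months. The largest knockout minus wild-type difference between 3' and 5' control probe sets was -0.15 over 3 ages, for Gapdh at P2 (exact permutation p = 0.2). At P2 and P10 alone it was -0.15 as well and no control separated the genotypes, while at 2 months Gapdh differed by -0.14 (exact permutation p = 0.0286, adjusted p = 0.22).

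Genes changed in one direction at all 3 ages lay near Nrl more often than others. Within 20 Mb of Nrl lay 6 of 20 such genes, 30% against 2.03% of other genes (Fisher's exact p = 2.39e-06), namely Parp2, Pnp, Hnrnpc, Chd8, Mir686 and Rb1, so DNA of another strain kept around the targeted locus may account for these. The same DNA could bear on the P2 calls, 10 of 141 of which lay there (Fisher's exact p = 0.000744), while the test did not pass for the P10 calls, 16 of 481 (p = 0.0685), or the 2 month calls, 22 of 742 (p = 0.105). The window leaves 14 of the genes changed at all 3 ages on other chromosomes or farther away, among them Pde6b, Rom1, Pdc, Abca4 and Gnat2. An effect of the missing Nrl on the 6 genes stays open as well, since how much DNA of another strain was kept at the locus is not known here.

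Of 11 lens genes the crystallins Crygb, Crygc and Crygs were lower in knockout retina at 2 months, and the list's call was lost with an estimated correlation (adjusted p = 0.374). A candidate explanation is lens tissue carried over in differing amounts. In the P2 and P10 arrays, where no such difference was called, 8 crystallin genes deviated from their group means together, with a median pairwise correlation of 0.774 over 16 arrays, as carried-over lens would give. Crystallins that vary together within the retina would give this as well, so it does not decide between them. The other lens genes differed less at 2 months, at 29.4 in wild type and 26.7 in knockout for Mip, 39.5 and 36.6 for Gja3 and 69.2 and 57.9 for Bfsp1. Crygs averaged 347 ± 101 in wild type and 132 ± 52.8 in knockout at 2 months. A change within the retina is not excluded, since retinal cells also express crystallins and this was not tested.

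Genes of glial reaction were higher in knockout retina at 2 months, with a list median of 0.59 (95% interval -0.04 to 1.13 over 14 genes). A lower share of rods in the RNA could raise the markers of every other cell type alike, but 28 bipolar, amacrine, horizontal and ganglion cell genes had a median of -0.0628 (95% interval -0.10 to -0.02) and the highest of them was 0.13. The first test asked whether the intervals of the 2 medians lay apart, which they did not. The list median minus that of the 28 genes, taken per array, was higher in all 4 knockout than in all 4 wild-type arrays, by 0.59 (exact permutation p = 0.0286). This second test was set after both medians were known, so it restates the rise and adds no support of its own. The 28 genes did not rise as a set, which argues against a lower rod share as the cause of the rise of the list as a whole. A change in glia, in state or in number, stays open.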

How the results depend on the processing

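Leaving out knockout and wild-type P2 replicate 1 together, the replicate number as a block over all ages and the test of the number were chosen only after the result was seen. No called gene among those whose results were recomputed, and no called list in the comparisons of knockout with wild type, changed direction. A count is taken as kept within 1.5 times its value, and a gene or list with the same direction on the same side of the threshold. With one replicate left out, 99 of 104 counts, 1347 of 1384 named gene results and 466 of 504 list results were kept in this sense, and under other settings 113 of 144, 1526 of 1555 and 290 of 336. The P2 count of 175 ranged from 84 to 552 with one replicate left out, was 88 without the pair (75 of them shared) and 41 with only the arrays compared. With array weights the counts were 414 at P2, 1401 at P10, and 486 and 475 for the knockout effect from P2 to P10 and from P10 to 2 months. At an adjusted p under 0.01 these 4 were 66, 400, 174 and 191. Counts of at least 2-fold were 10, 73 and 139 for knockout against wild type, 64, 63 and 135 for its change between ages (P10 to P2, 2 months to P10, 2 months to P2), 592 and 141 for wild-type and 504 and 169 for knockout maturation; the stricter criteria lower a count by construction, and for the others the cause was not tested. At P2 the cone list's adjusted p was 0.171 with an estimated correlation and ranged from 0.00388 to 0.118 with one replicate left out, the highest without knockout replicate 3. That of the rod list was 0.0128 by fry and 0.0493 without the pair, where its median was above 0 although camera's direction was down, and ranged from 0.0296 to 0.165. Deviations of same-numbered knockout and wild-type arrays of an age had correlations from -0.28 to 0.61, and 4 of 12 were best with their own number, so the numbers were not taken to pair samples. A shared effect of the number over the 24 arrays was present, since 1244 probe sets differed between numbers, against at most 2 with the numbers drawn anew within groups (100 numberings, the real one included); its source is not known here. With the number as a block within ages, counts were 229, 671 and 997 for knockout against wild type. With it as a block over all ages they were 464, 922 and 1246, and 432, 414 and 834 for the change of the knockout effect (P10 to P2, 2 months to P10, 2 months to P2). For maturation, where the number as a block was set before the data were examined, they were 4688 and 2340 in wild type and 4575 and 2827 in the knockout. The balance of higher and lower calls depended on the setting. Over settings with the same threshold, single replicates left out aside, the percentage of higher calls ran from 56.1 to 75.1 at P2, 50.1 to 67.7 at P10 and 54.4 to 59.8 at 2 months for knockout against wild type. It ran from 43.4 to 53.9, 46.9 to 56.5 and 46.4 to 52.0 for the change of its effect, from 46.2 to 57.5 and 40.8 to 49.8 for wild-type and from 45.2 to 56.3 and 40.0 to 44.9 for knockout maturation. With one replicate left out it crossed 50 at 2 months (49.0 without knockout replicate 4), for all 3 changes of the effect and for both wild-type steps. The number of arrays and dim signals limit what can be seen: 5540 probe sets lay under the table's median in every group.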

Other observations

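All of the genes in this part were chosen only after the result was seen. Of the called probe sets, 18 changed in opposite directions at 2 ages, 16 of them with 1 gene name. The glycolytic enzyme genes Pgk1 and Pgam1 changed by 0.35 and 0.31 at P2 and by -0.42 and -0.40 at 2 months. The metallothionein genes Mt1 and Mt2, which bind metals, changed by -0.55 and -0.41 at P2 and by 0.47 and 0.30 at 2 months. Zfp36l2, an RNA-binding protein gene, changed by 0.48 at P2, -0.98 at P10 and -1.88 at 2 months, and Fezf2, a neuronal transcription factor gene, by -0.60 at P2 and 0.36 at P10. Myo7a, a myosin gene, changed by -0.84 at P10 and 0.32 at 2 months.

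The small nucleolar RNA host gene Gas5 averaged 668 ± 40.5 in wild type and 588 ± 125 in knockout retina at P2, 545 ± 79.2 and 268 ± 81.3 at P10, and 615 ± 48.4 and 98.0 ± 8.57 at 2 months, by its brightest probe set. A dimmer Gas5 probe set read 86.0 ± 3.34 and 84.9 ± 5.21, 73.4 ± 2.26 and 67.8 ± 8.86, and 65.9 ± 4.63 and 58.5 ± 6.81 at these ages. Crybb2 was read by 2 probe sets. At 2 months the one that is brighter on average over the 24 arrays stood at 303 ± 6.29 in wild type and 291 ± 28.4 in knockout, and the other at 383 ± 101 and 129 ± 40.3. Xist, expressed in female cells, ran from 159 to 313 among the knockout and from 7.43 to 126 among the wild-type arrays at P2, from 168.5 to 287 and from 73.6 to 123 at P10, and from 8.90 to 209 and from 9.00 to 107 at 2 months. The Y-linked gene Eif2s3y ran from 28.4 to 88.5 and from 69.0 to 136 at P2, from 17.0 to 77.9 and from 63.5 to 77.2 at P10, and from 21.6 to 88.9 and from 25.8 to 126 at 2 months. Every wild-type P10 array thus read far above the lowest values of both genes, 7.43 and 17.0. So did the knockout P2 arrays except the lowest for Eif2s3y, the others reading at least 83.0. These values argue against single animals for those samples and for RNA of both sexes. The other groups held arrays low in either gene, and whether their replicates were pools stays open. Sex was not in the model. A difference in sex between the groups could therefore bear on other genes called at P2 and P10, which was not tested.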
